A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

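Copy number was measured by comparative genomic hybridization on 2 Agilent 2-colour tiling arrays of fission yeast. Per the labels, DNA of a sap1-1 revertant was labelled with Cy5 and DNA of the wild type with Cy3 on each array, both after digestion with AluI and RsaI. Both arrays lay on 1 slide, and dyes were not swapped, so that a dye effect of a probe cannot be removed. The revertants form 1 group of 2 replicates, numbered as in the labels, and the wild-type channel is the only control.

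Per the file headers, the authors' scanner images were quantified with Agilent Feature Extraction 10.10.1.1, which the submitters' processing notes also name. The deposited processed signals are intensities that this program had background-subtracted and dye-normalized with a linear factor per channel (0.136 and 0.517 for green and red in replicate 1, 0.137 and 0.460 in replicate 2), with a lowess factor of 0, per the file headers. The deposited log10 ratio of the scanner files equalled log10 of the red over the green processed signal within 0.001 (0 exceptions) and was used only as this check. The deposited flags, per the file headers, mark outlier, saturated and dim spots as 0 or 1. The authors' deposited series table held log2 ratios of the same arrays. It equalled the centred running mean over 5 neighbouring probes of log2(red / green) on all 3 chromosomes (r = 1, slope 1, 100% of values within 0.001), uncentred, for 41251 of the probes, and its column medians were -0.0030 and -0.01. Scale, centring and direction were settled by this comparison.

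The log2 ratio of the processed signals, red over green, was centred on the median of the array over all 41551 probes that were not controls. The medians before centring were 0.09 and 0.08. Probes with an outlier flag on either array were left out (10 in replicate 1 and 3 in replicate 2), and saturated probes were kept (388 and 395 in the green channel, 86 and 84 in the red). The median raw signals were 8318 and 8348 in the green channel and 2350 and 2577 in the red, and 41533 and 41543 probes were well above background in the red channel. Ratios rose with brightness: the dimmest 10% of the probes had a median of -0.26 and -0.24, and the brightest 10% had 0.15 and 0.22. No loess was applied in the main values, since true copy number shifts could go 1 way.

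Probes, 10 kb windows (median, at least 5 probes) and genes (mean, at least 3 probes) were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes, Benjamini-Hochberg at 0.05). An exact sign permutation of 2 arrays cannot give a p below 0.5, so that regions were described without a test. Windows of at least 0.5 in size on both arrays were counted. Segments were found by least-squares optimal partitioning with a penalty of 10 times the logarithm of the number of probes times the variance, at least 5 probes, and a call at 0.25 on both arrays. Fixed regions and gene lists were described by percentiles among 10000 random runs, sets or lists, the lists matched on tertiles of probe number. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, numba 0.67.0, biopython 1.88 and matplotlib 3.10.9 was used.

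The genome build of the probe positions is not given in the sources used here. The log ratio of a probe falls with its GC content, and this was used to compare positions with the ASM294v3 assembly, by correlating ratios with the GC content of 60 bp stretches in blocks of 200 kb. The best shift was -60 to 240 bp on the first 0.8 Mb of chromosome III and stayed in that range up to 1 Mb, but was about -840 bp on its right arm, -760 and then 4460 bp on chromosome I, and -780 and then -1700 bp on chromosome II, where the first 200 kb had -5060 bp at a weak correlation (r = -0.08). No position was converted. Positions of segments and windows are those of the array. Single genes were therefore tested only on the first 1 Mb of chromosome III, and elsewhere genes were described by the median of the probes within 5 kb on each side, a distance larger than these shifts except that of the first 200 kb of chromosome II, where the list genes reb1, ght4, ght7 and frp1 lie. Over these neighbourhoods limma gave every gene the same standard error, so that its calls do not use the agreement of the replicates. Counts of gene lists use these neighbourhoods, which departs from the planned test on own probes, and centromere intervals carry the same shifts.

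The limma step was checked on simulated data. With noise independent between arrays, 100% of the windows shifted by 0.5 or 1 were called, and 0.474% of 1054 unshifted windows. With probe positions shuffled, which keeps the effects that probes have on both arrays, 55.03% of the unshifted windows and 87.4% of 151 unshifted genes were called. A second error was therefore added after seeing the data, in which a window, gene or neighbourhood is compared with 20000 random sets of as many probes. Segments were tested on shuffled data too: shifts of 1 over 100 or 400 probes were found in 20 of 20 trials, those of 0.5 over 400 probes in 20 of 20, and those of 1 over 20 probes, 0.5 over 100 probes and 0.3 over 400 probes in 0 of 20 each, so that short or weak gains and losses can be missed.

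The named genes were fixed before the data were examined: the 15 highest and 15 lowest genes past limma with the same direction on both arrays, sap1, the telomere list, other list members past the test, and the first, last and listed genes of called segments, as well as the 5 highest and 5 lowest windows. Alternatives were normexp background correction with an offset of 50, loess within arrays, the authors' series table, only probes well above background, flagged spots kept, other window sizes, thresholds, penalties and probe minimums, and leaving out each replicate. Normexp was run on the median signals in place of the mean signals named in the plan.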

Results

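Genomic DNA of fission yeast (Schizosaccharomyces pombe, a haploid yeast with 3 chromosomes) was compared on 2 tiling arrays. Each array carried DNA of a sap1-1 revertant in the Cy5 channel and wild-type DNA in the Cy3 channel, so that a log2 ratio above 0 means more DNA in the revertant than in the wild type, relative to the median of the array. The sap1 gene encodes an essential DNA-binding protein that acts at replication fork barriers, and a revertant is a strain that has lost a mutant phenotype. The labels do not say whether the 2 revertants were isolated separately or whether both arrays were given the same wild-type DNA. Each array held 41551 probes, 1 about every 300 bp, and 41549 of them were well above background in the wild-type channel of each replicate. The number of arrays limits the precision. The p-values of limma rest on the spread between these 2 arrays, pooled in part over all features tested, and leave out the spread of the wild type. Comparisons with random probe sets use the spread between probes instead.

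The comparison asks which parts of the genome differ in copy number between the revertants and the wild type. The sap1-1 strain before reversion was not on these arrays, so that differences already present in it cannot be told apart from later ones. Both revertants carried a gain on the left arm of chromosome III that contained sap1 itself. From position 486901 to 615901 the median log2 ratio was 0.96 ± 0.01 (SD, n = 2), a 1.95-fold ratio, with 0.97 in replicate 1 and 0.95 in replicate 2 over 424 probes. The sap1 gene with 10 kb on each side had a median of 0.97 ± 0.05 (SD, n = 2; 74 probes), at percentile 99.61 among 10000 random runs of as many consecutive probes. Those runs could overlap the gain itself and the chromosome ends. The segmentation called no loss in either replicate.

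**Figure D1:**
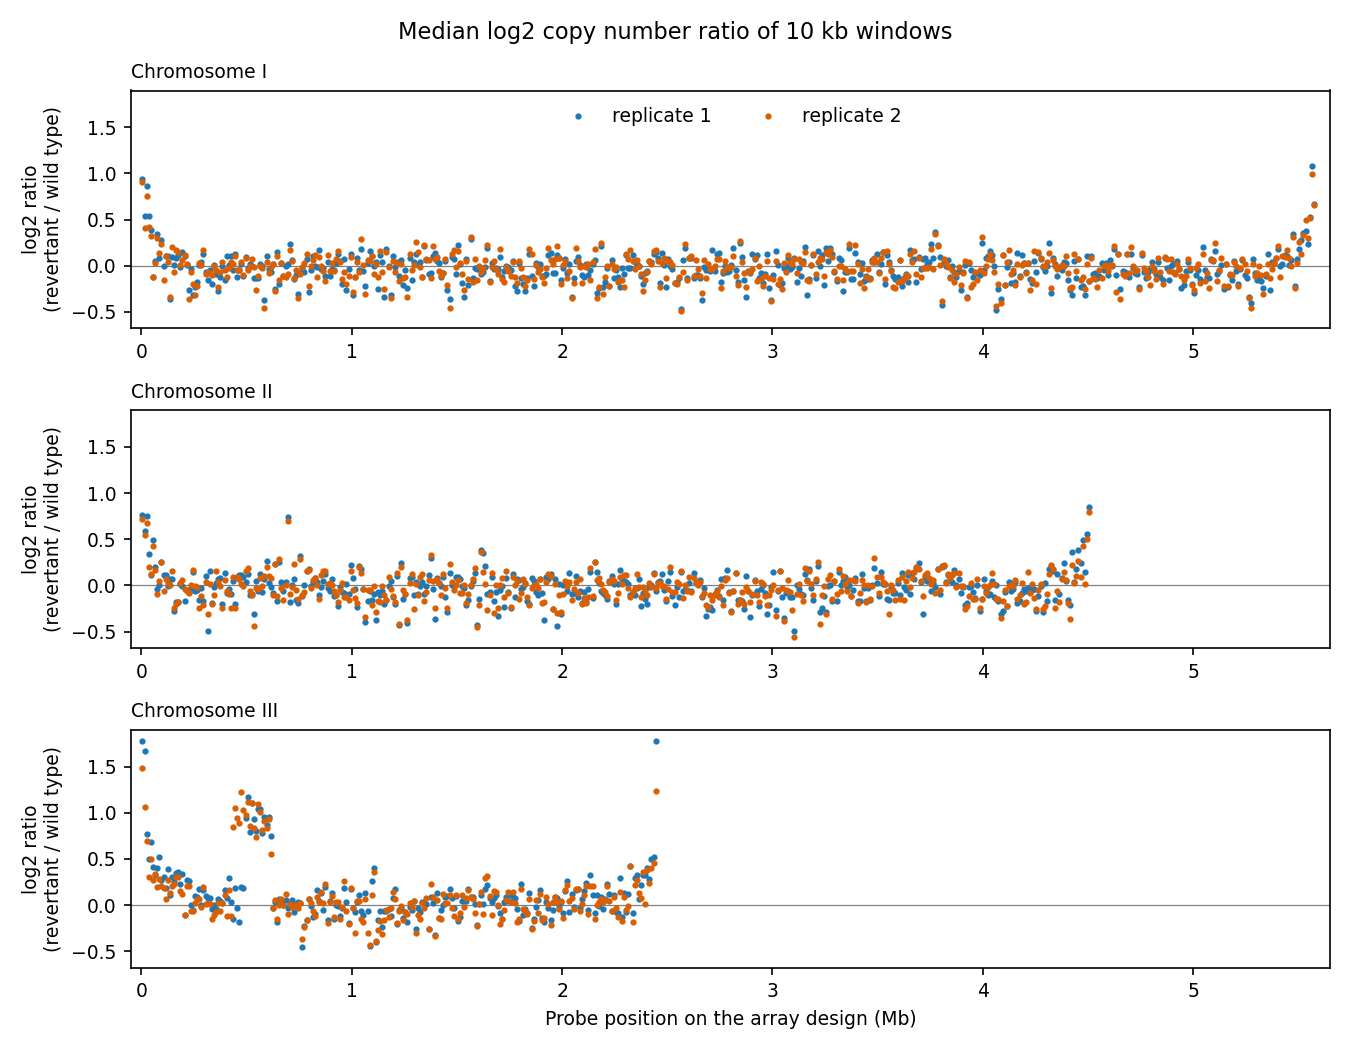
Median log2 ratio (vertical axis) of 10 kb windows against probe position in Mb (horizontal axis) on chromosomes I, II and III, with 1 point per replicate. The windows of the gain on chromosome III stand near 0.96 in both replicates, and the windows at all 6 chromosome ends lie above 0.

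The gain had different lengths in the 2 revertants. In replicate 1 it ran from 486901 to 615901 (129.3 kb), and in replicate 2 from 427201 to 615901 (189 kb), so that the right edge was shared and the left edges differed. In the stretch from 427201 to 486601 the median was 0.07 in replicate 1 and 0.98 in replicate 2 over 199 probes, and 100% of these probes were higher in replicate 2. The median difference between the replicates there was 0.97, while 9898 random runs of 199 probes that did not touch the stretch had differences from -0.17 to 0.06. Segmentation of replicate 2 minus replicate 1, chosen after seeing the data, found this stretch as 1 of 3 differing segments (429001 to 486601, 0.98). The other 2 were the ends of chromosome III, lower in replicate 2 by -0.34 from 1 to 24601 and by -0.46 from 2440801 to 2453701. With the mean of both replicates, which was the rule fixed before the data were examined, the gain was called from 471901 to 615901 (0.94 ± 0.04, SD, n = 2).

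**Figure D2:**
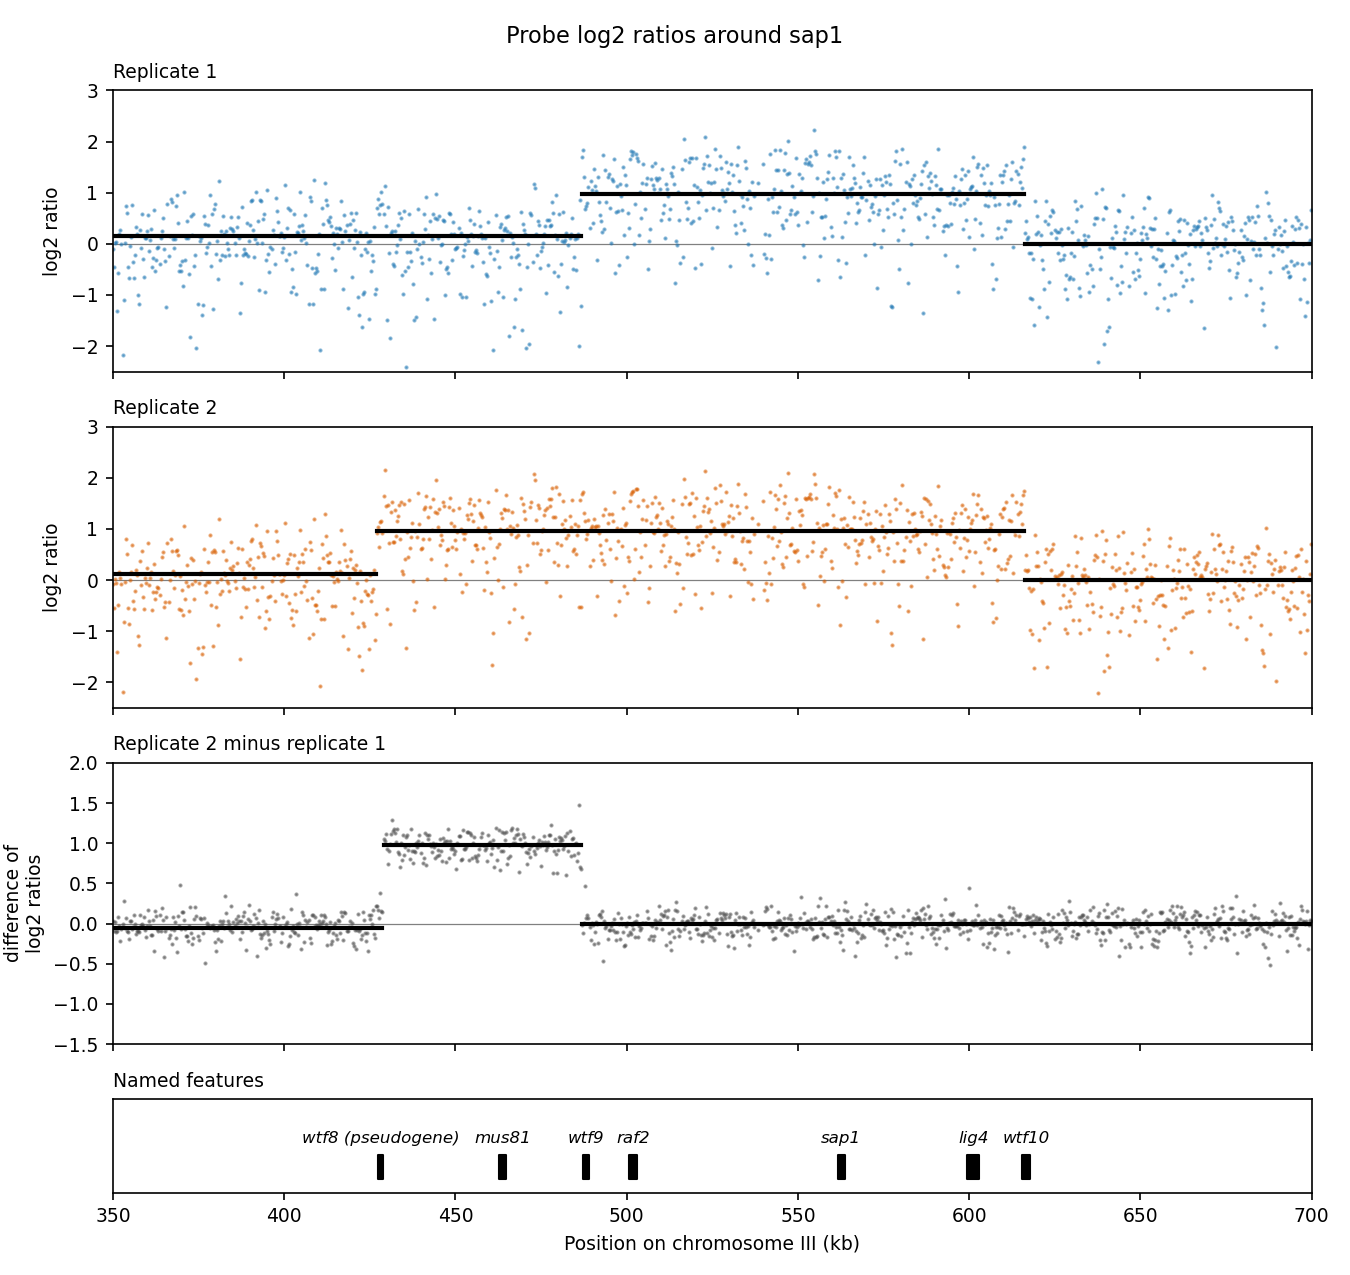
Log2 ratio of each probe (points) in replicate 1, in replicate 2 and as the difference replicate 2 minus replicate 1, against position in kb on chromosome III, with segment medians as black lines and named genes as bars below. The gain begins at 486901 in replicate 1 and at 427201 in replicate 2 and ends at 615901 in both, and the difference is 0.98 between 429001 and 486601.

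The edges of the gain called in each replicate lay at or next to repeated elements. The called left edge in replicate 1 was at or next to a long terminal repeat (LTR, the end sequence of a retrotransposon) at 486575 to 486925, beside wtf9, a member of the wtf family of spore killer genes and their antidotes. The called left edge in replicate 2 was 244 bp from the pseudogene wtf8 (427445 to 428763). The shared right edge at 615901 was at wtf10 (615387 to 617622). In simulated gains of 1 over 400 probes the edge error had a median of 150 bp and a 90th percentile of 1560 bp, so that the edges cannot be placed inside an element. The left edge called on the mean of both replicates (471901), which lies between the left edges of the replicates, was 1298 bp from the nearest such element, a tRNA gene. These gene positions are those of the ASM294v3 assembly, and probe positions on this part of chromosome III matched that assembly to within 240 bp.

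Single genes were tested on the first 1 Mb of chromosome III. Of the 49 protein-coding genes inside the gain of both replicates 44 were tested, and 43 of these were higher by limma (Benjamini-Hochberg adjusted p under 0.05), and the median gene ratio was 0.86. The exception was mis18, at -0.14 over 3 probes. Limma also called 165 of the 281 tested genes outside the gained stretches (69 higher, 96 lower), so that its calls are weak evidence by themselves. Against random sets of as many probes, 41 of the 44 genes in the gain were higher. sap1 (SPCC1672.02C, 561576 to 563766) had a mean of 0.62 ± 0.02 (SD, n = 2) over its 8 own probes, a 1.54-fold ratio with an adjusted p of 0.0055 from limma. SPCC1672.01, whose interval spans sap1, had 0.84 over 19 probes. Gene values are means over few probes and not medians as for the regions. Single probes outside the gains and the chromosome ends had an SD of 0.65. Differences between genes of the gain are therefore no evidence of different copy numbers. All 15 of the highest genes lay in the shared gain, with 3 to 17 probes each. They were rps1201 (a ribosomal protein gene, 1.62), raf2 (a component of the heterochromatin-forming CLRC complex, 1.33), med31 (a Mediator subunit, 1.23), eft202 (translation elongation factor 2, 1.21), mob2 (1.20), cox19 (1.17), ast1 (1.16), wtf9 (1.13), psg2 (1.10), bir1 (the survivin of the chromosomal passenger complex, 1.09), SPCC1183.02 (1.08), get4 (1.07), lig4 (the DNA ligase of end joining, 1.03), erv29 (1.01) and tcb1 (0.94). Their adjusted p from limma was at most 0.0055, and all 15 also stood out against random sets of as many probes. The first gene inside the segment called on the mean of both replicates was nap1 (over 7 probes, -0.0076 in replicate 1 and 0.95 in replicate 2, mean 0.47, adjusted p of 0.29), which lay in the stretch gained in replicate 2 alone, and the last was pmp31 (0.81 over 4 probes).

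The 25 tested genes inside the stretch gained in replicate 2 alone were each higher in replicate 2 than in replicate 1, by 0.89 to 1.10. Their median ratio was -0.12 in replicate 1 and 0.86 in replicate 2, and limma called none of them at an adjusted or an unadjusted p under 0.05 (0 of 25), since the replicates disagreed. Among them was mus81, which encodes a structure-specific endonuclease and was chosen after its values were seen, with 0.12 in replicate 1 and 1.11 in replicate 2 over 7 probes.

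None of the 351 genes tested on the first 1 Mb of chromosome III was lower against random sets of as many probes, while over the whole genome 10 of 5111 gene neighbourhoods (the gene with 5 kb on each side) were. Among the 15 lowest genes past limma were mrps8 (-0.93), tef101 (translation elongation factor 1 alpha, -0.93), rpb6 (-0.91), mdh1 (malate dehydrogenase, -0.84), thg1 (-0.64), rpn1302 (-0.64), taf5 (-0.63), sry1 (-0.62), mcm4 (a subunit of the replicative helicase, -0.62), naa20 (-0.62), dcr2 (-0.58), gcd1 (-0.57), SPCC757.05C (-0.54) and coq10 (-0.53). The adjusted p of the 15 was at most 0.020, yet 0 of the 15 stood out against random sets of as many probes, and none lay in a called segment. Over the 351 genes tested, 209 passed limma, 113 higher and 96 lower (142 and 48 with the authors' series table). With the median of the probes in place of the mean, 123 were higher and 60 lower. Unshifted genes in the shuffled data had a median of -0.11, so that testing means against 0 favours lower calls. Against random probe sets, an error chosen after seeing the data, 56 genes were higher and 0 lower. Of the 56, 41 lay in the shared gain, 7 in the stretch gained in replicate 2 alone, 1 (wtf10) partly in the gain and 7 outside. Those outside were bcd1 (0.74), SPCC613.01 (0.66), mae2 (0.57), SPCC613.03 (0.55), SPCC1235.01 (0.54), rng3 (0.50) and gem1 (0.46). The comparison with random sets uses the mean of both replicates and not their agreement.

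Across the genome, the 10 kb windows gave the same picture. At a median log2 ratio of at least 0.5 in both replicates, 28 windows were higher and 0 were lower (15 and 4 after loess within arrays). Of these, 13 lay in the shared gain, 14 within 50 kb of a chromosome end, and 1 elsewhere, at 690001 to 700000 of chromosome II (0.72 over 22 probes). In 100 shuffles of the probe positions, the median number of such windows was 0 and the highest was 4. Limma called 574 of the 1254 windows, 246 higher and 328 lower, but it called a median of 690 windows when positions were shuffled, so that this count does not separate regions from probe effects. Of 41538 probes, 33533 passed limma, 16606 higher and 16927 lower, with the same limit. The 5 highest windows past limma were 1 to 10000 (1.63 ± 0.21), 2440001 to 2450000 (1.51 ± 0.38), 10001 to 20000 (1.36 ± 0.42), 500001 to 510000 (1.14 ± 0.05) and 520001 to 530000 (1.10 ± 0.0016), all on chromosome III (SD, n = 2). The 5 lowest were 3100001 to 3110000 of chromosome II (-0.53 ± 0.05), 2560001 to 2570000 of chromosome I (-0.48 ± 0.02), 4060001 to 4070000 of chromosome I (-0.46 ± 0.03), 1590001 to 1600000 of chromosome II (-0.44 ± 0.02) and 1080001 to 1090000 of chromosome III (-0.44 ± 0.0076). Only the first 2 of these 5 were also lower against random probe sets.

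The ends of the chromosomes and the ribosomal DNA had higher ratios in the revertants. The first and last 50 kb of all chromosomes had a median of 0.51 ± 0.04 (SD, n = 2; 863 probes), above all 10000 random sets of scattered probes. Among random runs of consecutive probes, which are the closer match, the single ends lay at percentiles 97.97 to 99.2. The runs were drawn from whole chromosomes with the ends and the gain around sap1 left in. These percentiles therefore do not compare the ends with the rest of the genome alone. The highest single end was the left end of chromosome III (0.83 ± 0.18) and the lowest the left end of chromosome II (0.38 ± 0.05), with 0.62 ± 0.02 and 0.47 ± 0.04 at the left and right ends of chromosome I, 0.43 ± 0.02 at the right end of chromosome II and 0.50 ± 0.07 at the right end of chromosome III. The ribosomal DNA repeats at both ends of chromosome III had a median of 1.57 ± 0.31 (SD, n = 2; 74 probes), with 1.79 in replicate 1 and 1.35 in replicate 2. Of these 74 probes, 48 were saturated in either channel (38 in the wild-type channel of both arrays and 28 in the revertant channel of both), so that this ratio is inexact. Besides the gain around sap1, the segmentation called 5 gains, all at chromosome ends: 1 to 41101 (0.80) and 5518801 to 5574601 (0.46) of chromosome I, 4491601 to 4510501 of chromosome II (0.71), and 1 to 26701 (1.44) and 2437801 to 2453701 (1.38) of chromosome III. After loess within arrays, the ribosomal DNA fell to 0.70 and only 1 end gain was called, from 2364601 to 2453701 of chromosome III (0.31). This segment was longer and weaker than the one called at that end before, so that the size of the end ratios depends on the normalization. The end segment from 1 to 26701 of chromosome III held 0 complete protein-coding genes, and genes of the other end segments were not tested singly, because probe positions there were not matched to the assembly.

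Mitochondrial DNA had a higher ratio in the revertants. Its 61 probes had a median of 1.86 ± 0.17 (SD, n = 2), a 3.63-fold ratio, with 1.98 in replicate 1 and 1.73 in replicate 2, and 100% of them were above 0. After loess within arrays the median was 0.89, below the 0.91 of the sap1 region. Of the 61 probes, 36 were saturated in either channel. In 14 of the 61 probes the wild-type channel was saturated in both replicates, and in 28 the revertant channel was, so that their ratios are compressed or bounded.

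**Figure D3:**
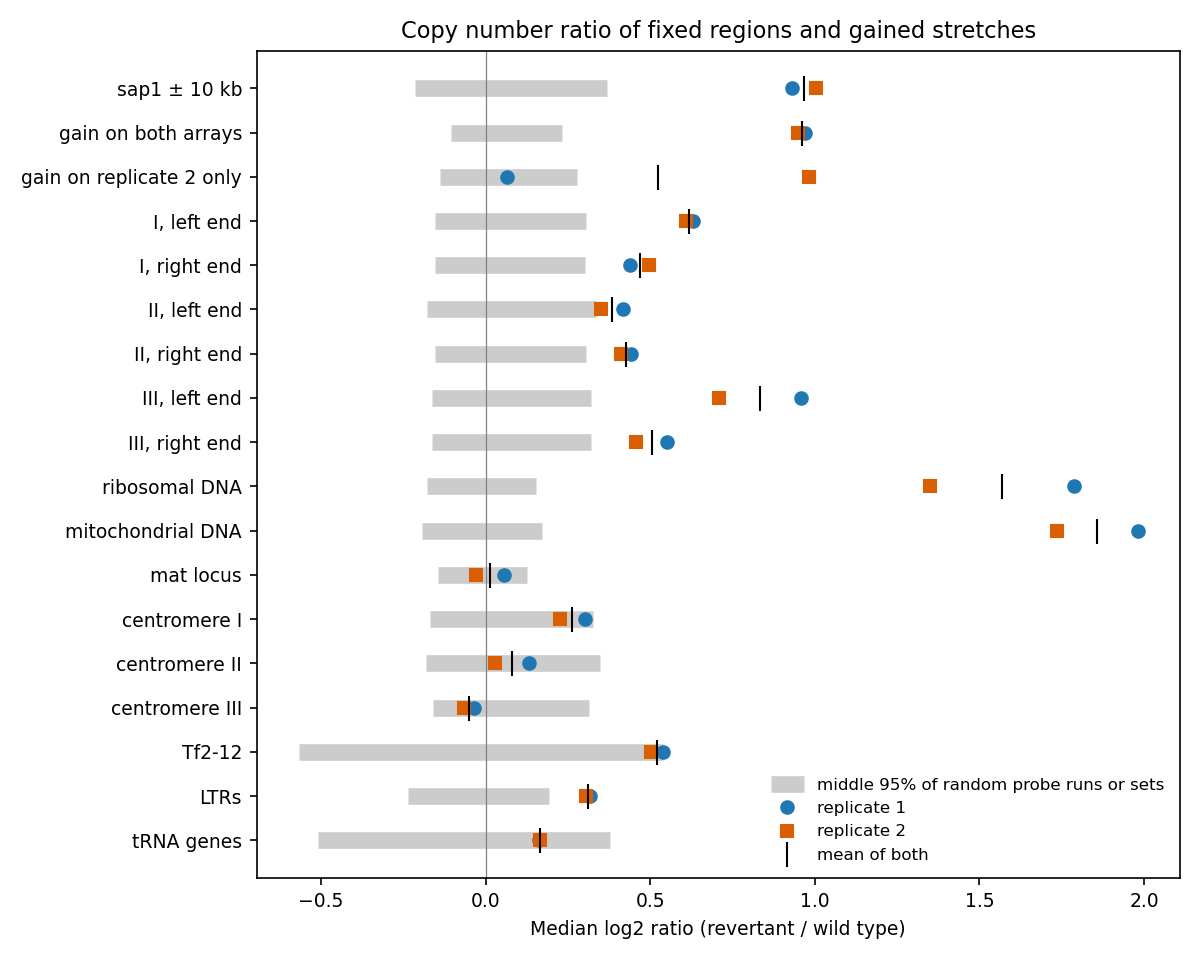
Median log2 ratio (horizontal axis) of fixed regions and of the gained stretches (rows) in replicate 1 (circles) and replicate 2 (squares), with their mean (vertical ticks). Grey bars span the middle 95% of 10000 random runs or sets of as many probes. The means of the mat locus, the 3 centromeres, Tf2-12 and the tRNA genes lie inside their grey bar and those of all other rows above it, and the mitochondrial genome has the highest mean at 1.86.

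The other regions had lower ratios or ratios that depended on the normalization. The mat locus, which determines mating type, had a median of 0.01 ± 0.06 (110 probes). The centromeres, taken as the longest stretch of each chromosome without a protein-coding gene, had 0.26 ± 0.05 on chromosome I, 0.08 ± 0.07 on chromosome II and -0.05 ± 0.02 on chromosome III, and 0 of these 3 lay outside the middle 95% of random runs. Of the 143 probes of the centromere of chromosome III, 45 were saturated in either channel. The other 98 had a median of 0.02, so that the sign of its ratio is open. On the first 1 Mb of chromosome III, LTRs had 0.31 ± 0.0091 (45 probes, percentile 99.94), the retrotransposon Tf2-12 had 0.52 ± 0.02 (10 probes, percentile 97.4; 0.11 after loess and 0.26 in the authors' series table) and tRNA genes had 0.17 ± 0.0020 (11 probes, percentile 78.92), all SD with n = 2. The random probes were drawn from all 3 chromosomes, and elements inside the gained stretches were not left out. These percentiles therefore do not separate the kind of element from its place on chromosome III. Whole chromosomes had medians of -0.026 ± 0.0016 (I), -0.019 ± 0.000010 (II) and 0.087 ± 0.0060 (III), and that of chromosome III was 0.028 without the called segments. Most probes lie on chromosomes I and II, and each array was centred on the median of all probes. These SDs therefore do not measure how precisely the copy number of a chromosome is known. No whole chromosome was near the ratio of 0.96 seen in the gain.

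The telomere genes, including those of shelterin, the complex that binds telomeres and is named in the title of the series, lay outside the gains. All 12 members were measured through the probes within 5 kb on each side of the gene, and their median was -0.07, at percentile 12.19 among 10000 lists matched on probe number. Over such neighbourhoods limma's moderation gave 1 standard error (0.05) to all genes, so that its calls are a cut on the mean at a size of 0.11 that does not use the agreement of the replicates, and 1964 of 5111 neighbourhoods passed it (38.4%; 831 higher, 1133 lower). Beyond this cut 1 telomere member was higher and 2 were lower, both over all genes and adjusted over the list alone. The lower members were poz1 (-0.40 ± 0.04) and rap1 (-0.23 ± 0.06), and the higher member was est1, a telomerase subunit (0.15 ± 0.09). The other values were 0.09 for taz1, -0.09 for tpz1, -0.05 for ccq1, -0.07 for pot1, -0.06 for rif1, -0.08 for stn1, -0.03 for ten1, 0.06 for trt1, the telomerase catalytic subunit, and -0.09 for tel1. Against random probe sets 0 members stood out, and the counts past the cut changed with the normalization (10 members after loess within arrays).

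In the other fixed lists, the members whose neighbourhoods stood out in either direction against random probe sets were sap1, lig4, raf2 and tlh1. Of 19 checkpoint and fork protection genes, 2 were higher and 2 lower past the same cut, with sap1 at 0.98 over its neighbourhood. The other higher member was mus81, which was gained in replicate 2 alone (-0.21 in replicate 1 and 0.86 in replicate 2 over its neighbourhood), so that it does not reflect both replicates. On its own probes mus81 stood out against random probe sets. Of 17 recombination genes measured 5 were higher and 1 lower, with lig4 at 0.89, and of 24 heterochromatin and CENP-B genes 5 higher and 5 lower, with raf2 at 1.07. The subtelomeric helicase gene tlh1, the 1 measured member of its list, had 0.92 ± 0.03 over its neighbourhood at the left end of chromosome I. Past the cut were 1 higher and 2 lower among 8 telomere anchoring genes, 2 higher and 8 lower among 33 origin firing and replisome genes, 3 higher and 2 lower among 18 cohesin and condensin genes, 2 higher and 8 lower among 23 chaperone and proteasome genes, 5 higher and 4 lower among 17 transporter genes (6 and 4 adjusted over the list alone) and 2 higher and 2 lower among 4 mating type genes. These counts are not evidence of a change in a list, given the share of all neighbourhoods past the cut. Adjusted over the list alone, the counts of all lists but the transporters were the same. The medians of these lists ran from -0.08 (chaperones and proteasome, percentile 1.82) to 0.03 (transporters, percentile 90.25), apart from tlh1. On their own probes, bqt3 (1.26-fold) was higher by limma, and mcm3 (0.78-fold), cnd2 (0.86-fold), smc6 (0.86-fold) and ght1 (0.87-fold) were lower, with adjusted p from 0.013 to 0.032. Also lower by limma was mcm4 (0.65-fold, adjusted p of 0.0055), which had a log2 ratio of 0.02 over its neighbourhood and was not called there. Against random probe sets 0 of these 6 stood out. The call of cnd2 reversed between these measures, since over its neighbourhood it was higher by limma (log2 ratio of 0.17, adjusted p of 0.0019) and is counted so above.

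The arrays shared most of their probe-to-probe pattern. Across 41538 probes, which are not independent replicates, the log2 ratios of the 2 arrays had Pearson's r = 0.97, and across 1254 windows r = 0.89. Without the gain and the ends, r across 38768 probes was 0.98, so that the correlation does not measure similarity in copy number. Effects of probes that both arrays share could raise it, and so could wild-type DNA common to both. These cannot be told apart here.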

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

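The pNSU probes, which the report does not describe on their own and the authors' series table does not list, carried a signal. They enter the centring and the counts over all probes. These 129 probes, named after 9 sequences that the files do not describe, had a median log2 ratio of 0.74 ± 0.05 (SD, n = 2), with 0.78 in replicate 1 and 0.71 in replicate 2. Of the 129, 37 were saturated in either channel, and the other 92 had a median of 0.55. Matched on wild-type brightness, by subtracting the mean of the 50 background probes nearest in brightness, the median was 0.64 over 126 probes in range. Outside the called segments, chromosome means lay below the medians, and ratios were centred on the median, so that matched values run somewhat high. By sequence, the values ran from 0.23 and 0.32 (pNSU71, 29 probes) to 1.56 and 1.40 (pNSU28, 2 probes) in replicates 1 and 2. No control array was analysed here, and the comparison is with 0.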

How the results depend on the processing

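No paired analysis was possible because there is 1 group. The probe-set error, the saturation, brightness and segments-left-out settings and the difference between replicates were chosen after seeing the data; the other settings were planned. The correction for probe GC content was not run, since probe sequences were not used here. The cause of the shifts below was not tested. The gain around sap1 was called under every normalization, penalty and threshold tried, and segments that differ between the replicates numbered 3 under all 7 normalizations and filters. Nearly all probes were well above background, so that signal over background limits little here.

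Limma's treat at 0.25 left 21585 probes, 43 windows (6 in the median shuffle) and 80 of 351 genes, while with positions shuffled it called 25.8% of unshifted genes, so that this count does not separate genes from probe effects. The probe-set error left 45 windows and 56 genes, of which 4 windows and 7 genes lay in the stretch gained in replicate 2 alone. Limma called 1391 windows of 5 kb and 275 of 20 kb, with more and fewer windows tested. The size rule took 96 windows of 5 kb (61 higher, 35 lower), 15 of 20 kb, 107 at a threshold of 0.25 (60 higher, 47 lower) and 7 at 1. Segments numbered 2 after loess, those around sap1 (0.83) and at the right end of chromosome III (0.31). Without replicate 1 or 2, the size rule took 34 to 35 windows and 6 to 7 segments were called; with 1 array limma gives a value and no test.

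Chromosomes I, II and III had medians of -0.024, -0.015 and 0.075 with normexp, -0.014, -0.015 and 0.059 with loess, and -0.020, -0.012 and 0.075 in the authors' series table. Means in place of medians were -0.13, -0.12 and 0.024, and without called segments the medians were -0.033, -0.023 and 0.028. Without saturated probes chromosomes I and II had -0.024 and -0.016, and chromosome II had -0.019 with only probes well above background or with flagged spots kept. Leaving out a replicate gave -0.027 to -0.025 for chromosome I, -0.019 for chromosome II and 0.083 to 0.091 for chromosome III.

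After loess, the sap1 region was 0.91, the shared gain 0.87, the chromosome ends 0.36, ribosomal DNA 0.70 and mitochondrial DNA 0.89. Matched on brightness, these were 1.06 (sap1 region), 1.04 (shared gain), 1.23 (ribosomal DNA) and 1.66 (mitochondrial DNA), values that run somewhat high as said for the pNSU probes. Without saturated probes the ends were 0.45 and ribosomal DNA 1.17. The shared gain was 0.93 with normexp and 0.98 in the series table, and the ends were 0.85 over 20 kb and 0.34 over 100 kb. Tf2-12 fell from 0.52 to 0.11 after loess and 0.26 in the series table. Leaving out a replicate gave 0.93 to 1.00 for the sap1 region, 0.95 to 0.97 for the shared gain, 0.49 to 0.54 for the ends, 1.35 to 1.79 for ribosomal DNA and 1.73 to 1.98 for mitochondrial DNA, and 0.07 to 0.98 for the stretch gained in replicate 2.

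Of the single genes, 2 that did not pass the test changed sign: ago1 after loess (-0.00069) and ght5 in the series table (0.0070). All 15 highest genes passed under each setting, and of the 15 lowest 14 passed after loess or in the series table. Counts of list members past limma moved by over 1.5 times in 31 of the cases tried, for the telomere list from 3 to between 6 and 10 with normexp, loess, the series table or saturated probes left out.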

Other observations

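The tests of brightness, GC content, saturation and edges were chosen after the genome profile had been examined. Apart from the edge test, the bounds were written before the values were computed. The bounds of the edge test were written after the genes of the region, wtf genes included, had been seen, and do not count as set in advance.

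The gain around sap1 was set against technical explanations. Matched on wild-type brightness, its median was still at least 1.02 on either array, and adjusted for the GC content of 77 windows elsewhere on the first 1 Mb of chromosome III it was 0.88, so that neither brightness nor GC content accounts for it. The matched value runs somewhat high, as said for the pNSU probes. Of the probes of the gain, 89.2% had a ratio above 0, against 48.5% elsewhere. Since the segment was called by its high median, this share was largely fixed by the call. It is therefore no independent test of whether a few deviant probes made the gain. A candidate explanation, as a hypothesis found on these data, is that both revertants carry a second copy of a segment with sap1. Whether that copy accounts for the reversion was not tested, as these arrays measure DNA only. Whether it was already present before the reversion cannot be told, since no unreverted sap1-1 strain was on these arrays.

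The edges of the gain may mark where the segment was copied. The 3 distinct edges called in single replicates lay a mean of 81.3 bp from the nearest wtf gene, LTR, Tf2 element or tRNA gene, against a median of 10651 bp for random positions, which puts the edges at repeated elements (wtf genes, LTRs, Tf2, tRNA genes) at percentile 0.01 of 10000 draws. Since the element classes were chosen with these genes in view, the percentile is not a blind test. Recombination between repeats is a hypothesis that was not tested here: the nearest elements were an LTR or a wtf pseudogene on the left and a wtf gene on the right, and their sequence similarity and orientation were not compared. Whether the differing left edges arose from separate events was not tested either, and the labels leave it open. In simulated gains of 1 over 400 probes the edge error reached 1560 bp at the 90th percentile, the difference between the replicates put the left edge of replicate 2 at 429001 in place of 427201, and only 3 edges were available. The left edge called on the mean of both replicates, 1298 bp from the nearest element, was not part of the test.

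The mitochondrial DNA ratio was weighed against saturation and dye bias. Probes saturated in neither channel had a median of 1.78, and the brightness-matched median was at least 1.49 on either array with 59 of 61 probes in range, both far above 0, so that neither is the whole cause. Loess moved the value from 1.86 to 0.89, so that its size stays open. A difference in mitochondrial DNA content between the strains and one between the DNA preparations cannot be separated here, and no biological explanation was tested.

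For the chromosome ends the evidence is less clear. End probes saturated in neither channel had a median of 0.44, between the bounds set for and against saturation (0.25 and 0.5), so that part of the ratio may come from saturated probes. The brightness-matched median was at least 0.48 on either array. Matching subtracts a mean of background probes, while ratios were centred on the median. Outside the called segments the means of chromosomes I, II and III (-0.14, -0.13 and -0.061) lay below their medians (-0.033, -0.023 and 0.028). Matched values therefore run high, and the test does not settle how much of the end ratio is dye bias. For ribosomal DNA the corresponding values were 1.17 without saturated probes and at least 1.06 on either array after matching. More repeats per cell in the revertants and differences in labelling of repeated DNA stay open, and neither was tested.

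The ends of chromosome III also differed between the replicates: ribosomal DNA was lower in replicate 2 by a median of -0.35, and 2.7% of its probes were higher in replicate 2. As 48 of its 74 probes were saturated in either channel, the size of this difference is inexact, and probes saturated in neither channel had 1.41 in replicate 1 and 0.92 in replicate 2. Mitochondrial DNA differed in the same direction, by -0.30 (0% of probes higher in replicate 2).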
